A study of Escherichia coli with 18 samples.

How the data were processed

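The series measured RNA of Escherichia coli K-12 MG1655 wild type and an rpoS knock-out with an antisense genome array. Cells came from biofilms grown for 72 h in glass flow cells, from planktonic exponential cultures (8 h) and from planktonic stationary cultures (12 h), all in MOPS minimal medium with 0.2% glucose. Each of the 6 groups held 3 arrays from separate experiments, 18 arrays in all. Per the labels, RNA was stabilised with RNAprotect and purified with an RNeasy kit, and cDNA was labelled with biotin. The rpoS probe set was read in every group as a check of the labels.

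The deposited table holds 1 intensity value per probe set and array, on a linear scale, made by the authors in a way that is not given in the sources used here: probe summary, background and scaling are all unstated. The table holds no detection calls, and the arrays were not quantile normalized. It lists 7312 probe sets: 22 controls, 2886 intergenic regions, 59 of phages and plasmids and 4345 of genes. The 7290 probe sets other than controls were tested. Gene names came from the platform table through RefSeq gene identifiers of the assembly ASM584v2: 4192 probe sets matched exactly 1 K-12 gene (4148 genes, 41 of them with more than 1 probe set), 41 matched several and 112 matched none. A gene with several probe sets was read by its brightest. Probe sets that share sequence between genes are uncertain as to gene.

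Array medians were 39.1 to 78.4 and upper quartiles 129 to 217. Intergenic probe sets had medians of 13.9 to 35.0 and gene probe sets 67.7 to 129, while the highest control for an absent sequence read 27.4, so values near 30 cannot be told from background. The most intense value was 13635, and 1 to 21 probe sets per array read 0. Correlations within groups were 0.984 to 0.996 in knock-out biofilm, 0.838 to 0.923 in wild-type biofilm, 0.821 to 0.930 in knock-out exponential phase, 0.983 to 0.994 in wild-type exponential phase, 0.969 to 0.974 in wild-type stationary phase and 0.873 to 0.939 in knock-out stationary phase. The median residual SD on the log2 scale was 0.123, 0.493, 0.434, 0.140, 0.194 and 0.371 in the same order.

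Values were taken as log2(value + 16), and limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all 18 arrays with moderated t-tests (eBayes). Adjusted p values are Benjamini-Hochberg over the 7290 probe sets, and a probe set was called at an adjusted p under 0.05. Folds are on this scale and understate genes of low intensity. Where a group mean lay near 30, the log2 change depends on the added constant, and no fold is printed. Errors of log2 changes are standard errors, means of intensity carry the SD of 3 arrays. The 12 comparisons were knock-out against wild type in each growth condition, each pair of growth conditions within each strain, and the 3 differences of knock-out effects between growth conditions. The share of probe sets whose 3 values in 1 group all lay outside the range of the other was counted for each comparison, with 10% as the share that chance gives.

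For gene lists, camera of limma with a preset correlation between genes of 0.01 tested 36 lists of at least 5 measured members, with adjusted p over the 36 lists of a comparison, and again with the correlation estimated from the data. The lists were written from textbook knowledge of K-12 genes. Members were counted over all genes and with p adjusted over the list alone. Genes named are rpoS everywhere, up to 10 of the largest changes each way in the 6 comparisons of strains and within the wild type, up to 4 members of the RpoS list and of each called list, the 10 largest in each difference of knock-out effects and up to 3 each way within the knock-out. The largest changes were taken among called genes with groups that did not overlap and with 1 symbol. A gene outside this rule is marked as chosen after the data were seen.

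The groups, comparisons, threshold, gene lists, rule for named genes and the first set of alternatives were chosen before the data were examined. These alternatives were an added constant of 1 or 64, quantile normalization, centring on the 75th percentile, leaving out the dimmest 25% of probe sets, only probe sets with 1 symbol, a fold of at least 2, a variance trend, the replicate number as a block, only the groups compared, each array left out in turn and an estimated correlation. Added after the data were seen were a block for the presence of Dap spike-in RNA, fits within the arrays with and without it, and a fit without replicate 1 of the knock-out exponential and stationary groups. The Dap probe sets had a mean of 1250 to 5229 on 9 arrays (knock-out biofilm 1, 2 and 3, wild-type biofilm 2 and 3, knock-out exponential 1 and 3, knock-out stationary 1 and 3) and at most 39.1 on the other 9. In the text, "the block" is this spike-in block, and values in spike-in arrays or in arrays without are from fits to arrays of that kind alone.

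The fit was tested on simulated data with 200 changed probe sets in the biofilm comparison of strains: 10%, 32%, 66% and 100% of 50 changes each were called at log2 0.5, 1, 2 and 3, and 8 of 7090 unchanged probe sets were called. A list of 54 genes shifted by log2 0.5 was called, as was 1 of 35 lists without a shift. These rates need not hold for the real arrays. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Probe-level files were not used here.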

Results

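The rpoS transcript (b2741) was near background in every knock-out array, at 7.33 to 35.1, with means of 22.1 in biofilm, 23.8 in exponential phase and 26.6 in stationary phase. In the wild type it averaged 1052 ± 778 in biofilm, 2650 ± 105 in exponential phase and 1065 ± 230 in stationary phase (mean ± SD, n = 3). Wild-type biofilm replicate 1 held only 156, against 1438 and 1562 in replicates 2 and 3. The change from wild type to knock-out was log2 −4.27 ± 0.59 in biofilm (adjusted p = 1.8e-04), −6.14 ± 0.59 in exponential phase (adjusted p = 3.3e-05) and −4.65 ± 0.59 in stationary phase (adjusted p = 3.0e-05). Every wild-type array exceeded the knock-out, biofilm replicate 1 by the least. With 1 array left out, the biofilm difference lay between −5.32 and −3.72.

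**Figure D1:**
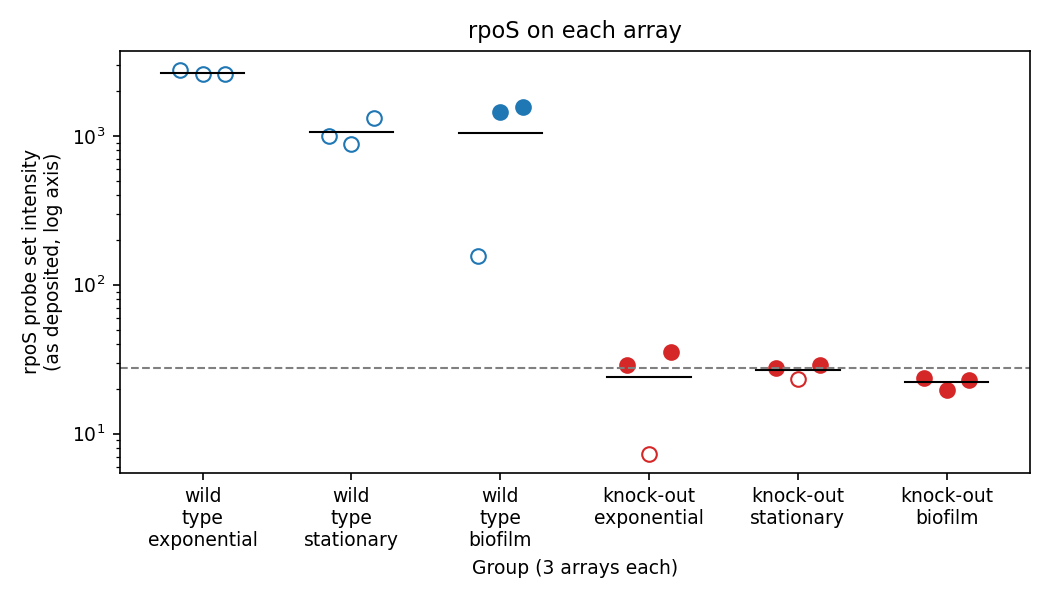
Intensity of the rpoS probe set on each of the 18 arrays, by group, on a log axis. Each point is 1 array.

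Between the strains, 3233 probe sets were called in biofilm, 230 in exponential phase and 1947 in stationary phase. Such counts test no difference in effect. Within the wild type, 3604 separated biofilm from exponential phase, 2123 biofilm from stationary phase and 2462 the planktonic phases. Within the knock-out, these numbers were 402, 740 and 0. Of the 191 list calls over all comparisons, all rest on the preset correlation of camera, and none passed with an estimated correlation. The centre of all probe sets depended on the scaling: medians moved from −0.27 to −0.09 (quantile) and −0.48 (75th percentile) for the strains in biofilm, from 0.01 to 0.04 and 0.12 in exponential phase and from 0.08 to −0.02 and −0.17 in stationary phase. In the wild type they moved from 0.23 to 0.12 and 0.59 (biofilm over exponential), from 0.43 to 0.14 and 0.28 (biofilm over stationary) and from −0.03 to 0.11 and 0.47 (stationary over exponential). In the knock-out, biofilm over stationary moved from −0.02 to −0.04 and −0.13, and stationary over exponential from −0.06 to 0.00 and 0.08. For the differences of knock-out effects they moved from −0.39 to −0.15 and −0.36 (biofilm minus stationary), from −0.27 to −0.14 and −0.59 (biofilm minus exponential) and from 0.02 to −0.10 and −0.34 (stationary minus exponential).

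**Figure D2:**
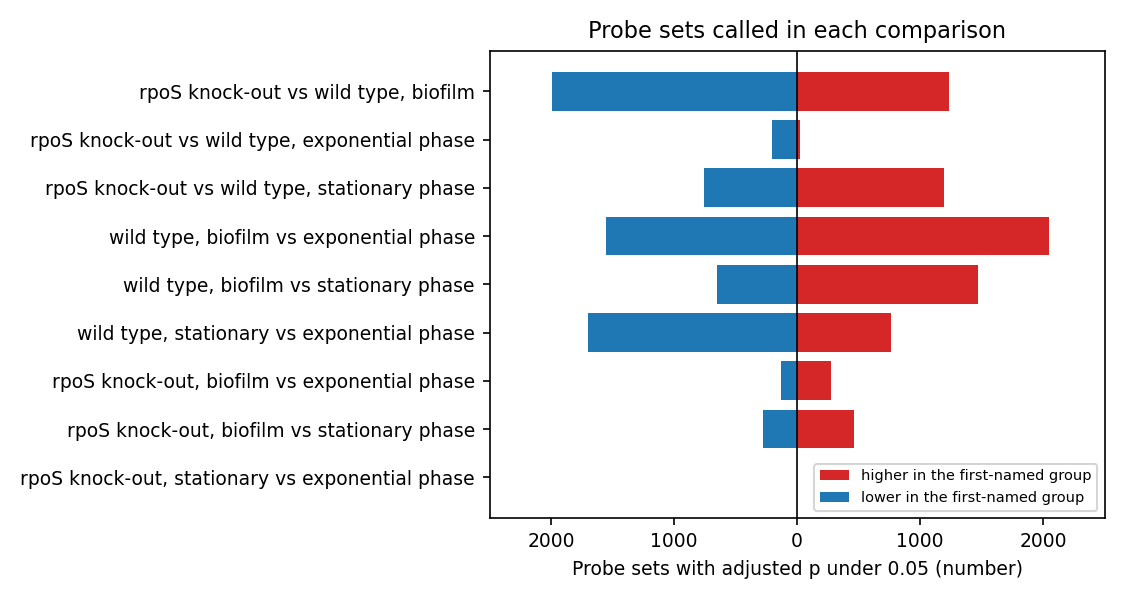
Probe sets called higher and lower in each comparison at an adjusted p under 0.05. Each group held 3 arrays.

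In biofilm, rpoS fell in the knock-out as given above, and grxA (b0849, which encodes glutaredoxin 1) rose 33.0-fold, to a mean of 2784 ± 392 against 84.3 ± 59.3 in the wild type (log2 5.04 ± 0.48, adjusted p = 1.7e-05, n = 3 each). The biofilm-associated gene tabA (b4252) rose 23.1-fold (1303 ± 301 against 40.8 ± 10.7, log2 4.53 ± 0.36, adjusted p = 5.0e-06). The porin gene ompF (b0929, log2 4.09 ± 0.38, adjusted p = 1.7e-05), the major fimbrial subunit gene fimA (b4314, log2 3.93 ± 0.48, adjusted p = 9.1e-05) and the flagellin gene fliC (b1923, log2 3.89 ± 0.56, adjusted p = 2.3e-04) were also among the largest rises. The copper efflux gene cusC (b0572) rose by log2 4.61 ± 0.59 and yagU (b0287) by 4.72 ± 0.52. On the other side, yjfN (b4188) fell to 99.6 ± 45.1 against 2650 ± 2082 (log2 −4.18 ± 0.76, adjusted p = 1.1e-03). The biofilm stress gene bsmA (b4189) fell to 210 ± 72.1 against 4008 ± 2822 (log2 −3.82 ± 0.89, adjusted p = 4.4e-03). The galactofuranose transport gene ytfQ (b4227) was lower at log2 −3.82 ± 0.89 and yiaG (b3555) at −3.17 ± 0.43.

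RpoS-dependent general stress genes were lower in the knock-out biofilm, with 2 higher and 33 lower of 71 over all genes, 2 and 33 over the list alone (median log2 −0.79, −0.87 with the block, −0.97 in spike-in arrays, adjusted p = 4.9e-03, adjusted p = 0.592 with an estimated correlation). Without wild-type biofilm replicate 2 this call ended, at an adjusted p of 0.077. The transketolase gene tktB (b2465, −2.42 ± 0.32) and the transaldolase gene talA (b2464, −2.36 ± 0.47) were among the members that fell, while cfa (b1661), for cyclopropane fatty acid synthase, rose by log2 2.94 ± 0.65. Gad acid resistance genes were higher, with 6 of 15 higher over all genes and 6 over the list alone (median log2 1.5, 1.32 with the block, 0.64 in spike-in arrays, 0.98 after quantile normalization, adjusted p = 1.6e-03, adjusted p = 0.592 with an estimated correlation). Of these, the regulator gene gadW (b3515) rose by log2 2.65 ± 0.54. Of the 6 biofilm arrays only wild-type replicate 1 lacks spike-in RNA, so the medians in spike-in arrays are also those without it, where 2 of the 15 Gad genes were higher.

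All ATP synthase genes rose in the knock-out biofilm, with 9 of 9 higher over all genes and 9 over the list alone (median log2 2.51, 2.16 with the block, 1.82 in spike-in arrays, adjusted p = 3.2e-06, adjusted p = 0.592 with an estimated correlation). Ribosomal protein genes were higher, with 21 of 54 higher over all genes and 20 over the list alone (median log2 1.14, 0.77 with the block, 0.31 in spike-in arrays, 0.35 after quantile normalization, adjusted p = 7.8e-09, adjusted p = 0.592 with an estimated correlation). Of these, rpsT (b0023) changed by log2 3.53 ± 0.43. Heat shock and protein folding genes had 12 of 20 higher over all genes and 12 over the list alone (median log2 1.14, 0.88 with the block, 0.68 in spike-in arrays, 0.53 after quantile normalization, adjusted p = 2.8e-05, adjusted p = 0.592 with an estimated correlation). Fatty acid biosynthesis genes had 10 of 14 higher over all genes and 10 over the list alone (median log2 1.56, 1.26 with the block, 1.17 in spike-in arrays, adjusted p = 2.2e-05, adjusted p = 0.592 with an estimated correlation). Arginine biosynthesis genes had 11 of 16 higher over all genes and 11 over the list alone (median log2 1.42, 1.27 with the block, 0.99 in spike-in arrays, adjusted p = 1.9e-04, adjusted p = 0.592 with an estimated correlation).

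Type 1 fimbriae genes were higher in the knock-out biofilm, with 6 of 9 higher over all genes and 6 over the list alone (median log2 1.42, 1.27 with the block, 1.14 in spike-in arrays, adjusted p = 1.6e-03, adjusted p = 0.592 with an estimated correlation). Of these, fimI (b4315) changed by log2 3.60 ± 0.48 and fimC (b4316) by 2.40 ± 0.44. Colanic acid genes were lower, with 12 of 21 lower over all genes and 12 over the list alone (median log2 −0.92, −1.04 with the block, −1.03 in spike-in arrays, adjusted p = 1.9e-04, adjusted p = 0.592 with an estimated correlation). Of these, wcaL (b2044) changed by log2 −1.83 ± 0.51 and wcaI (b2050) by −1.62 ± 0.34. Phosphate starvation genes were lower too, with 1 higher and 16 lower of 29 over all genes, 1 and 17 over the list alone (median log2 −1.04, −1.18 with the block, −1.09 in spike-in arrays, adjusted p = 3.5e-03, adjusted p = 0.592 with an estimated correlation). Of these, phoE (b0241) changed by log2 −1.84 ± 0.35 and phnD (b4105) by −1.69 ± 0.33. Iron acquisition genes had 14 of 36 lower over all genes and 14 over the list alone (median log2 −0.56, −0.67 with the block, −0.75 in spike-in arrays, adjusted p = 2.3e-03, adjusted p = 0.592 with an estimated correlation). Of these, the ferric citrate transport gene fecC (b4289) changed by log2 −2.06 ± 0.26.

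By limma, 1237 probe sets were higher and 1996 lower in the knock-out biofilm, in 764 and 1106 genes, but by at least 2-fold 1106 were higher and 1057 lower. Without wild-type biofilm replicate 3, 1495 were higher and 1460 lower. The 2 groups did not overlap in 58.7% of probe sets, against 10% by chance. With the block 1128 were higher and 2155 lower, and within the spike-in arrays 736 and 2056. The share called higher was 38.3%, and 27.4% with 75th percentile centring. In all, 22 lists were called, of which 19 kept the call with the block and 19 within the spike-in arrays.

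In exponential phase, rpoS fell in the knock-out, and tabA again rose, 26.1-fold (1785 ± 1053 against 47.3 ± 14, log2 4.71 ± 0.36, adjusted p = 2.2e-06, n = 3 each). The biofilm regulator gene bssR (b0836) rose from its low wild-type level (1115 ± 722 against 72.1 ± 6.41, log2 3.40 ± 0.59, adjusted p = 3.4e-03). The ribosome-associated factor gene raiA (b2597) rose 8.29-fold (5788 ± 1830 against 668 ± 152, log2 3.05 ± 0.43, adjusted p = 8.0e-04). The periplasmic stress gene osmY (b4376) fell 22.5-fold (44.9 ± 27.2 against 1255 ± 104, log2 −4.49 ± 0.45, adjusted p = 4.7e-05). The genes yiaG, elaB (b2266), ygaM (b2672) and yeaG (b1783) were lower at log2 −3.99 ± 0.43, −3.94 ± 0.60, −3.48 ± 0.36 and −3.39 ± 0.50. The pyrimidine leader gene pyrL (b4246) was lower at log2 −3.70 ± 0.59 and the uracil permease gene uraA (b2497) at −3.01 ± 0.55.

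General stress genes that depend on RpoS fell in exponential phase, with 25 of 71 lower over all genes and 34 over the list alone (median log2 −1.12, −1.41 with the block, −1.0 in arrays without spike-in, adjusted p = 1.8e-25, adjusted p = 0.259 with an estimated correlation). Of these, talA was lower at log2 −3.55 ± 0.47. Acid resistance genes of the Gad list fell as well, with 7 of 15 lower over all genes and 11 over the list alone (median log2 −1.69, −2.16 with the block, −1.45 in arrays without spike-in, adjusted p = 6.7e-12, adjusted p = 0.259 with an estimated correlation). The glutamate decarboxylase genes gadA (b3517, 67.7 ± 44.1 against 2035 ± 1438, log2 −4.34 ± 0.91, adjusted p = 0.0142) and gadB (b1493, log2 −3.65 ± 0.84, adjusted p = 0.0265) lost their calls without knock-out exponential replicate 3, wild-type exponential replicate 1 or wild-type exponential replicate 3. Flagellar and chemotaxis genes were higher, with 4 of 54 higher over all genes and 10 over the list alone (median log2 0.73, 0.61 with the block, 1.01 in arrays without spike-in, adjusted p = 3.9e-13, adjusted p = 0.259 with an estimated correlation). Pyrimidine biosynthesis genes were lower, with 5 of 12 lower over all genes and 6 over the list alone (median log2 −1.73, −2.48 with the block, −2.68 in arrays without spike-in, adjusted p = 7.3e-08, adjusted p = 0.449 with an estimated correlation). Purine biosynthesis genes had 4 of 16 lower over all genes and 11 over the list alone (median log2 −1.66, −2.37 with the block, −2.33 in arrays without spike-in, adjusted p = 3.9e-09, adjusted p = 0.449 with an estimated correlation).

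By limma, 26 probe sets were higher and 204 lower in the knock-out in exponential phase, 213 of them by at least 2-fold, in 22 and 108 genes. The groups did not overlap in 23.6% of probe sets. With the block 90 were higher and 370 lower. Within the arrays without spike-in RNA the knock-out had 1 array, so no count is read there. The count was 111 without wild-type exponential replicate 1 and 105 without replicate 3, 9 of them higher in each, while 46 and 74 were higher without knock-out exponential replicates 1 and 3. The share called higher was 11.3%, and 26.0% with 75th percentile centring. Of 13 called lists, 12 kept the call with the block.

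In stationary phase, rpoS fell in the knock-out, and the stress kinase gene yeaG fell to background, at 34.6 ± 7.95 against 3305 ± 1016 (log2 −6.00 ± 0.50, adjusted p = 5.7e-07, n = 3 each). The gene yeaH (b1784) was lower at log2 −5.49 ± 0.32, osmY at −5.52 ± 0.45 (27.2 ± 23.5 against 1933 ± 988) and the universal stress gene uspB (b3494) at −5.04 ± 0.47 (27.6 ± 6.33 against 1447 ± 386). Large rises were seen in the porin genes nmpC (b0553, 3779 ± 1184 against 55.2 ± 19.0, log2 5.72 ± 0.44, adjusted p = 2.3e-07) and ompF (5670 ± 704 against 130 ± 21.9, log2 5.29 ± 0.38, adjusted p = 1.3e-07). The transport genes artJ (b0860, arginine) and livJ (b3460, branched-chain amino acids) rose by log2 5.64 ± 0.62 and 5.39 ± 0.36, and the ferritin gene ftnA (b1905) by 5.53 ± 0.50. The cytochrome oxidase gene cyoD (b0429) rose by 5.12 ± 0.46, and fimA by 4.88 ± 0.48.

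RpoS-dependent general stress genes fell most widely here, with 49 of 71 lower over all genes and 53 over the list alone (median log2 −1.99, −2.58 with the block, −1.96 in arrays without spike-in, adjusted p = 2.6e-28, adjusted p = 0.221 with an estimated correlation). Gad acid resistance genes were lower, with 6 of 15 lower over all genes and 6 over the list alone (median log2 −1.21, −1.57 with the block, −1.59 in arrays without spike-in, adjusted p = 6.7e-04, adjusted p = 0.509 with an estimated correlation). Of these, gadA was lower at log2 −3.64 ± 0.91. Genes of heat shock and protein folding had 5 of 20 lower over all genes and 5 over the list alone (median log2 −0.85, −1.17 with the block, −0.65 in arrays without spike-in, −1.62 after quantile normalization, adjusted p = 6.2e-04, adjusted p = 0.509 with an estimated correlation). Of these, the small heat shock gene ibpB (b3686) changed by log2 −2.87 ± 0.51. Iron acquisition genes were lower, with 1 higher and 9 lower of 36 over all genes, 1 and 10 over the list alone (median log2 −0.40, −0.49 with the block, −0.54 in arrays without spike-in, −0.65 with 75th percentile centring, adjusted p = 5.0e-04, adjusted p = 0.310 with an estimated correlation). The OxyR and SoxRS genes had 5 higher and 9 lower of 29 over all genes, 5 and 9 over the list alone (median log2 −0.09, −0.43 with the block, −0.55 in arrays without spike-in, −0.41 after quantile normalization, −0.34 with 75th percentile centring, −0.33 without knock-out exponential and stationary replicate 1, adjusted p = 0.0160, adjusted p = 0.509 with an estimated correlation). Of these, the iron-sulphur assembly gene sufD (b1681) changed by log2 −4.59 ± 0.25.

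All ATP synthase genes rose in the stationary knock-out, with 9 of 9 higher over all genes and 9 over the list alone (median log2 3.88, 3.73 with the block, 3.71 in arrays without spike-in, adjusted p = 2.1e-08, adjusted p = 0.310 with an estimated correlation). Of these, atpB (b3738) rose from background (1631 ± 416 against 28.2 ± 18.7, log2 5.30 ± 0.55, adjusted p = 4.6e-06). All NADH dehydrogenase I genes rose too, with 13 of 13 higher over all genes and 13 over the list alone (median log2 2.93, 2.81 with the block, 3.23 in arrays without spike-in, adjusted p = 1.4e-10, adjusted p = 0.310 with an estimated correlation). TCA cycle and glyoxylate shunt genes had 16 of 18 higher over all genes and 16 over the list alone (median log2 3.23, 2.79 with the block, 3.46 in arrays without spike-in, adjusted p = 2.4e-09, adjusted p = 0.509 with an estimated correlation). Of these, the isocitrate dehydrogenase gene icd (b1136) changed by log2 3.76 ± 0.34 and sdhB (b0724) of succinate dehydrogenase by 4.35 ± 0.66. Ribosomal protein genes had 44 of 54 higher over all genes and 49 over the list alone (median log2 2.33, 1.53 with the block, 2.09 in arrays without spike-in, adjusted p = 6.2e-14, adjusted p = 0.509 with an estimated correlation). Of these, rplW (b3318) changed by log2 4.21 ± 0.72. Arginine biosynthesis genes had 13 of 16 higher over all genes and 14 over the list alone (median log2 2.35, 1.70 with the block, 2.60 in arrays without spike-in, adjusted p = 1.7e-05, adjusted p = 0.509 with an estimated correlation). Carbon-limitation transport and catabolism genes had 24 higher and 1 lower of 55 over all genes, 25 and 2 over the list alone (median log2 1.62, 1.49 with the block, 2.35 in arrays without spike-in, adjusted p = 4.5e-05, adjusted p = 0.509 with an estimated correlation).

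By limma, 1193 probe sets were higher and 754 lower in the knock-out in stationary phase, 1663 of them by at least 2-fold, in 789 and 456 genes. In 44.4% of probe sets the groups did not overlap. With the block 1008 were higher and 855 lower. Within the arrays without spike-in RNA the knock-out had 1 array here too, so no count is read. The share called higher was 61.3%, and 45.0% with 75th percentile centring. Of 16 called lists, 16 kept the call with the block.

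Genes that fell in the knock-out in all 3 growth conditions included osmY, at log2 −1.49 in biofilm, −4.49 in exponential phase and −5.52 in stationary phase, and talA, at −2.36, −3.55 and −4.67. The transketolase gene tktB stood at −2.42, −2.59 and −3.81, the catalase gene katE (b1732) at −1.52, −3.0 and −1.30, and the trehalose phosphatase gene otsB (b1897) at −1.85, −2.90 and −4.82, the last 2 genes being chosen after the data were seen. The sulphur assembly gene sufD stood at −2.39, −1.24 and −4.59. In total 45 probe sets fell in all 3 conditions, where 5.78 would share the call if the conditions were independent. With the block, where more probe sets fell in each condition, 74 did. In biofilm and stationary phase 286 fell in both (206 if independent, Fisher p = 2.5e-11), and in exponential and stationary phase 95 (21.1, Fisher p = 2.5e-41). In biofilm and exponential phase 54 fell in both (55.9 if independent, Fisher p = 0.811), and 96 with the block. Rises shared by biofilm and stationary phase numbered 545 (202 if independent, Fisher p = 5.4e-150). In biofilm and exponential phase 15 rose in both (4.41, Fisher p = 3.1e-06), in exponential and stationary phase 11 (4.25, Fisher p = 1.5e-03), and in all 3 conditions 6 (0.722). Genes next to each other in operons are not independent, so these Fisher p values are too small.

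Within the wild type, rpoS was lower in biofilm than in exponential phase (log2 −1.86, adjusted p = 0.018), though only by −0.81 without biofilm replicate 1 (adjusted p = 0.025). The small heat shock gene ibpB rose from background in biofilm (3348 ± 2082 against 33.2 ± 2.89, log2 5.80 ± 0.51, adjusted p = 2.5e-06, n = 3 each). The biofilm regulator gene bssR rose 36.8-fold (3742 ± 2116 against 72.1 ± 6.41, log2 5.20 ± 0.59, adjusted p = 1.8e-05). The hydrogenase genes hyaB (b0973) and hyaD (b0975) rose by log2 4.83 ± 0.59 and 4.97 ± 0.83, and hycE (b2721) of formate hydrogenlyase by 4.36 ± 0.61. The oxoglutarate dehydrogenase gene sucA (b0726) fell to background (32.0 ± 11.7 against 1589 ± 369, log2 −5.07 ± 0.44, adjusted p = 2.2e-06). The cytochrome oxidase genes cyoD (35.4 ± 22.5 against 1833 ± 229, log2 −5.26 ± 0.46, adjusted p = 2.2e-06) and cyoA (b0432, log2 −4.75 ± 0.58) fell as well. The succinate dehydrogenase gene sdhC (b0721) was lower at log2 −4.71 ± 0.73, livJ at −5.13 ± 0.36 and pyrL at −4.99 ± 0.59.

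Anaerobic respiration and fermentation genes were higher in wild-type biofilm than in exponential phase, with 40 higher and 0 lower of 60 over all genes, 43 and 1 over the list alone (median log2 1.98, 2.24 with the block, 1.52 in arrays without spike-in, adjusted p = 8.9e-11, adjusted p = 0.386 with an estimated correlation). Genes of the TCA cycle and glyoxylate shunt fell, with 16 of 18 lower over all genes and 16 over the list alone (median log2 −3.73, −4.07 with the block, −4.02 in arrays without spike-in, adjusted p = 3.1e-12, adjusted p = 0.386 with an estimated correlation). ATP synthase genes all fell, with 9 of 9 lower over all genes and 9 over the list alone (median log2 −3.19, −3.84 with the block, −4.61 in arrays without spike-in, adjusted p = 4.9e-07, adjusted p = 0.386 with an estimated correlation). Of these, atpB was lower at log2 −3.99 ± 0.55. NADH dehydrogenase I genes had 12 of 13 lower over all genes and 12 over the list alone (median log2 −2.09, −1.96 with the block, −2.54 in arrays without spike-in, adjusted p = 6.7e-08, adjusted p = 0.386 with an estimated correlation). Ribosomal protein genes had 28 of 54 lower over all genes and 29 over the list alone (median log2 −1.41, −2.07 with the block, −2.99 in arrays without spike-in, −0.87 after quantile normalization, adjusted p = 2.4e-09, adjusted p = 0.720 with an estimated correlation). Of these, rpsT changed by log2 −4.40 ± 0.43 and rpmH (b3703) by −3.50 ± 0.23.

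Pyrimidine biosynthesis genes were lower in wild-type biofilm than in exponential phase, with 1 higher and 11 lower of 12 over all genes, 1 and 11 over the list alone (median log2 −3.06, −3.84 with the block, −3.51 in arrays without spike-in, adjusted p = 2.5e-05, adjusted p = 0.533 with an estimated correlation). Of these, pyrC (b1062) was lower at log2 −4.04 ± 0.66. Iron acquisition genes were higher, with 19 of 36 higher over all genes and 21 over the list alone (median log2 0.85, 0.77 with the block, 0.67 in arrays without spike-in, adjusted p = 1.1e-03, adjusted p = 0.386 with an estimated correlation). Of these, feoB (b3409) changed by log2 1.84 ± 0.44. Colanic acid genes had 12 of 21 higher over all genes and 13 over the list alone (median log2 0.86, 0.74 with the block, 0.65 in arrays without spike-in, adjusted p = 4.8e-03, adjusted p = 0.533 with an estimated correlation). After quantile normalization this call ended (adjusted p = 0.078). General stress genes that depend on RpoS were not called, with 11 higher and 17 lower of 71 over all genes, 10 and 17 over the list alone (median log2 −0.27, adjusted p = 0.447, adjusted p = 0.926 with an estimated correlation).

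By limma, 2048 probe sets were higher and 1556 lower in wild-type biofilm than in exponential phase, in 1161 and 913 genes, but by at least 2-fold 1158 were higher and 1379 lower. The groups did not overlap in 59.5% of probe sets. With the block 1445 were higher and 1553 lower. Within the arrays without spike-in RNA biofilm had only replicate 1, so no count is read there. The share called higher was 56.8%, and 72.9% with 75th percentile centring. Of 14 called lists, 13 kept the call with the block.

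Between wild-type biofilm and stationary phase, rpoS was not called (log2 −0.54, adjusted p = 0.48, and 0.51 without biofilm replicate 1). The nitrate reductase gene narH (b1225) rose from background in biofilm (1348 ± 1201 against 33.4 ± 6.98, log2 4.45 ± 0.71, adjusted p = 4.4e-04, n = 3 each). The hydrogenase maturation gene hypA (b2726) rose 21-fold (2401 ± 1578 against 77.8 ± 11.3, log2 4.40 ± 0.55, adjusted p = 5.9e-05). The genes ydfZ (b1541) and feoA (b3408), the latter for ferrous iron uptake, rose by log2 4.57 ± 0.99 and 4.23 ± 0.77. The stress genes osmY (75.8 ± 38.7 against 1933 ± 988, log2 −4.41 ± 0.45, adjusted p = 8.4e-06) and yahO (b0329, 74.6 ± 54.0 against 1764 ± 901, log2 −4.46 ± 0.49, adjusted p = 1.7e-05) were lower in biofilm. The manganese uptake gene mntH (b2392) was lower at log2 −4.07 ± 0.22, the acetyl-CoA synthetase gene acs (b4069) at −4.01 ± 0.95 and the trehalose synthesis gene otsA (b1896) at −3.61 ± 0.41.

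RpoS-dependent general stress genes were lower in wild-type biofilm than in stationary phase, with 4 higher and 36 lower of 71 over all genes, 7 and 36 over the list alone (median log2 −1.01, −1.40 with the block, −2.58 in arrays without spike-in, adjusted p = 3.8e-18, adjusted p = 0.448 with an estimated correlation). OxyR and SoxRS oxidative stress genes were lower, with 3 higher and 14 lower of 29 over all genes, 3 and 16 over the list alone (median log2 −1.40, −1.60 with the block, −2.03 in arrays without spike-in, adjusted p = 9.4e-07, adjusted p = 0.448 with an estimated correlation). Of these, soxS (b4062) changed by log2 −3.31 ± 0.82 and trxC (b2582) by −2.56 ± 0.32. Anaerobic respiration and fermentation genes were higher, with 28 of 60 higher over all genes and 34 over the list alone (median log2 1.48, 1.66 with the block, 0.92 in arrays without spike-in, adjusted p = 1.4e-05, adjusted p = 0.801 with an estimated correlation). Of these, hycF (b2720) changed by log2 3.61 ± 0.39 and narG (b1224) by 3.28 ± 0.59. TCA cycle and glyoxylate shunt genes were lower, with 9 of 18 lower over all genes and 9 over the list alone (median log2 −1.38, −1.78 with the block, −1.60 in arrays without spike-in, adjusted p = 1.1e-07, adjusted p = 0.801 with an estimated correlation). Fatty acid degradation genes had 4 of 9 lower over all genes and 4 over the list alone (median log2 −1.91, −1.68 with the block, −1.95 in arrays without spike-in, adjusted p = 4.9e-03, adjusted p = 0.801 with an estimated correlation). Ribosomal protein genes were higher, with 31 of 54 higher over all genes and 38 over the list alone (median log2 1.5, 0.83 with the block, 0.15 in arrays without spike-in, adjusted p = 9.1e-06, adjusted p = 0.801 with an estimated correlation). The 0.15 in arrays without spike-in rests on biofilm replicate 1 alone. ATP synthase genes had 7 of 9 higher over all genes and 8 over the list alone (median log2 1.48, 0.99 with the block, 0.44 in arrays without spike-in, adjusted p = 0.0115, adjusted p = 0.801 with an estimated correlation). This call ended with the block (adjusted p = 0.087) and without wild-type biofilm replicate 2 (adjusted p = 0.053).

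By limma, 1472 probe sets were higher and 651 lower in wild-type biofilm than in stationary phase, 1363 of them by at least 2-fold, in 884 and 389 genes. In 47.6% of probe sets the groups did not overlap. With the block 755 were higher and 601 lower. Within the arrays without spike-in RNA biofilm again had only replicate 1, so no count is read. The count was 1415 without wild-type biofilm replicate 3, and 1048, 1345 and 1285 without wild-type stationary replicates 1, 2 and 3. The share called higher was 69.3%, with quantile normalization 45.5% and with 75th percentile centring 57.3%. Of 12 called lists, 8 kept the call with the block.

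Wild-type biofilm differed from both planktonic phases in the same direction at 868 probe sets that were higher (462 genes) and 303 that were lower (174 genes). The nitrate reductase genes narH (log2 4.06 over exponential phase, 4.45 over stationary phase) and narG (4.04 and 3.28), hypA (3.63 and 4.40), hycE (4.36 and 3.44) and ibpB (5.80 and 3.08) were higher than in both. Lower than in both were osmY (−3.90 and −4.41), sucA (−5.07 and −2.60) and yahO (−2.54 and −4.46). If the 2 comparisons were independent, 414 higher and 139 lower would be shared. They share the biofilm arrays, so they are not independent. With the block 458 were higher and 304 lower. The higher count was 1311 without wild-type biofilm replicate 1, 427 without biofilm replicate 3, and 358, 502 and 461 without wild-type stationary replicates 1, 2 and 3.

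From wild-type exponential to stationary phase, rpoS was not called (log2 −1.32, adjusted p = 0.10, n = 3 each), though groups did not overlap. The aspartate carbamoyltransferase gene pyrB (b4245) fell 99.9-fold (52.5 ± 12.4 against 6751 ± 178, log2 −6.64 ± 1.11, adjusted p = 2.7e-04). The ATP synthase gene atpB fell to background (28.2 ± 18.7 against 2763 ± 150, log2 −6.08 ± 0.55, adjusted p = 1.5e-06). The branched-chain amino acid gene ilvC (b3774) fell 63.1-fold (43.0 ± 9.22 against 3680 ± 136, log2 −5.98 ± 0.83, adjusted p = 5.4e-05). The glutamate synthase gene gltB (b3212) was lower at log2 −5.73 ± 0.74, ftnA at −5.90 ± 0.50 and the methionine synthase gene metE (b3829) at −5.5 ± 1.02. Rises included bssR (2485 ± 295 against 72.1 ± 6.41, log2 4.82 ± 0.59, adjusted p = 1.8e-05) and yjbJ (b4045, 1513 ± 712 against 55.9 ± 4.02, log2 4.31 ± 0.39, adjusted p = 1.5e-06). The genes yjfN, yjfY (b4199) and bssS (b1060) rose by 4.16 ± 0.76, 4.50 ± 0.31 and 4.08 ± 0.69.

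General stress genes that depend on RpoS were higher in wild-type stationary phase, with 34 higher and 2 lower of 71 over all genes, 38 and 3 over the list alone (median log2 1.14, 2.03 after quantile normalization, adjusted p = 3.2e-11, adjusted p = 0.465 with an estimated correlation). All 6 arrays lack spike-in RNA, so the block leaves these medians as they are. Ribosomal protein genes fell, with 53 of 54 lower over all genes and 53 over the list alone (median log2 −3.0, adjusted p = 7.0e-19, adjusted p = 0.465 with an estimated correlation). Of these, rplW was lower at log2 −5.40 ± 0.72. ATP synthase genes all fell, with 9 of 9 lower over all genes and 9 over the list alone (median log2 −4.66, adjusted p = 1.6e-08, adjusted p = 0.391 with an estimated correlation). NADH dehydrogenase I genes had 13 of 13 lower over all genes and 13 over the list alone (median log2 −3.06, adjusted p = 1.2e-09, adjusted p = 0.391 with an estimated correlation). Purine biosynthesis genes had 16 of 16 lower over all genes and 16 over the list alone (median log2 −3.39, adjusted p = 3.0e-08, adjusted p = 0.465 with an estimated correlation). Of these, guaA (b2507) changed by log2 −5.21 ± 0.78. Pyrimidine biosynthesis genes had 10 of 12 lower over all genes and 10 over the list alone (median log2 −4.07, adjusted p = 3.1e-05, adjusted p = 0.465 with an estimated correlation). Branched-chain amino acid genes had 13 of 14 lower over all genes and 13 over the list alone (median log2 −2.81, adjusted p = 8.3e-06, adjusted p = 0.465 with an estimated correlation). Heat shock and protein folding genes were higher, with 5 of 20 higher over all genes and 5 over the list alone (median log2 0.68, 1.38 after quantile normalization, 1.18 with 75th percentile centring, adjusted p = 3.3e-03, adjusted p = 0.560 with an estimated correlation). Of these, clpB (b2592) changed by log2 2.27 ± 0.49. Iron acquisition genes had 11 of 36 higher over all genes and 11 over the list alone (median log2 0.48, 0.73 after quantile normalization, 0.99 with 75th percentile centring, adjusted p = 1.5e-04, adjusted p = 0.391 with an estimated correlation).

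By limma, 763 probe sets were higher and 1699 lower in wild-type stationary than in exponential phase, 2062 of them by at least 2-fold, in 480 and 1055 genes. The groups did not overlap in 65.3% of probe sets. With the block 2591 were called, and with only these 6 arrays in the fit 4109. The share called higher was 31.0%, with quantile normalization 48.1% and with 75th percentile centring 67.6%. Of 21 called lists, 19 kept the call with the block.

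**Figure D3:**
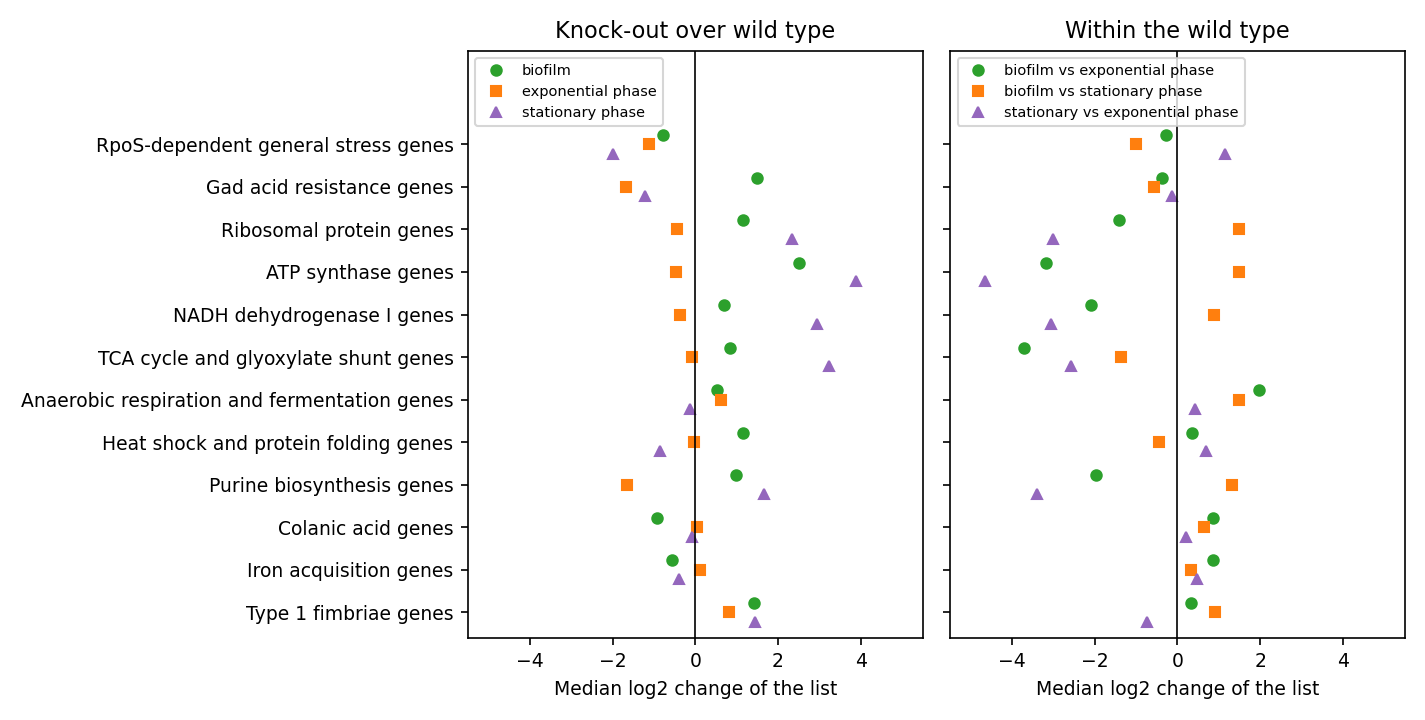
Median log2 change of gene lists between the strains (left) and between growth conditions of the wild type (right).

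Within the knock-out, rpoS stayed near background in all 3 growth conditions. The gene ibpB rose from background in exponential phase to a high level in biofilm (5113 ± 258 against 32.8 ± 20.8, log2 6.79 ± 0.51, adjusted p = 7.2e-07, n = 3 each). The glutamate decarboxylase gene gadA rose 85.1-fold (6225 ± 482 against 67.7 ± 44.1, log2 6.41 ± 0.91, adjusted p = 3.9e-04). The genes hyaD and narH rose by log2 5.88 ± 0.83 and 5.33 ± 0.71. The succinate dehydrogenase gene sdhC fell to 19.7 ± 6.72 against 1454 ± 1420 (log2 −4.58 ± 0.73, adjusted p = 1.0e-03), and the malate dehydrogenase gene mdh (b3236) was lower at log2 −3.81 ± 0.24. Acid resistance genes of the Gad list were higher in biofilm, with 10 of 15 higher over all genes and 14 over the list alone (median log2 2.87, 2.75 with the block, 2.89 in spike-in arrays, adjusted p = 1.5e-16, adjusted p = 0.104 with an estimated correlation). Anaerobic respiration and fermentation genes had 21 of 60 higher over all genes and 27 over the list alone (median log2 1.28, 1.57 with the block, 2.07 in spike-in arrays, adjusted p = 8.4e-23, adjusted p = 0.104 with an estimated correlation). Genes of heat shock and protein folding had 7 of 20 higher over all genes and 12 over the list alone (median log2 1.22, 1.03 with the block, 0.95 in spike-in arrays, adjusted p = 3.2e-13, adjusted p = 0.161 with an estimated correlation). Genes of the TCA cycle and glyoxylate shunt were lower, with 14 of 18 lower over all genes and 18 over the list alone (median log2 −2.86, −3.09 with the block, −3.83 in spike-in arrays, adjusted p = 1.8e-24, adjusted p = 0.104 with an estimated correlation). RpoS-dependent general stress genes had 14 of 71 higher over all genes and 15 over the list alone and a mean log2 of 0.79 (median log2 0.03, −0.13 with the block, −0.01 in spike-in arrays, 0.08 after quantile normalization, 0.06 with 75th percentile centring, 0.08 without knock-out exponential and stationary replicate 1, adjusted p = 2.6e-03, adjusted p = 0.790 with an estimated correlation). The median thus changed sign with the block and within the spike-in arrays.

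By limma, 274 probe sets were higher and 128 lower in knock-out biofilm than in exponential phase, 377 of them by at least 2-fold, in 173 and 84 genes. In 26.7% of probe sets the groups did not overlap. The count was 391 with the block and 365 within the spike-in arrays, and 259, 245 and 238 without knock-out biofilm replicates 1, 2 and 3. Of 16 called lists, 15 kept the call with the block and 12 within the spike-in arrays.

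From stationary phase to biofilm in the knock-out, rpoS stayed near background, at means of 26.6 and 22.1, while narH rose from background (4134 ± 153 against 30.8 ± 11.3, log2 6.50 ± 0.71, adjusted p = 2.5e-05, n = 3 each). The small heat shock gene ibpB also rose from background (5113 ± 258 against 28.9 ± 10.6, log2 6.86 ± 0.51, adjusted p = 6.0e-07). The gene ydfZ rose by log2 5.97 ± 0.99 and gadA by 5.45 ± 0.91. The acetyl-CoA synthetase gene acs (9.85 ± 3.00 against 2217 ± 1734, log2 −5.73 ± 0.95, adjusted p = 1.1e-03) and sdhC (19.7 ± 6.72 against 2288 ± 814, log2 −5.95 ± 0.73, adjusted p = 8.4e-05) fell. Every gene of the TCA cycle and glyoxylate shunt list fell, with 18 of 18 lower over all genes and 18 over the list alone (median log2 −3.99, −4.10 with the block, −3.86 in spike-in arrays, adjusted p = 2.9e-26, adjusted p = 0.175 with an estimated correlation). Anaerobic respiration and fermentation genes were higher, with 29 of 60 higher over all genes and 36 over the list alone (median log2 1.88, 2.0 with the block, 1.99 in spike-in arrays, adjusted p = 4.1e-20, adjusted p = 0.219 with an estimated correlation). Gad acid resistance genes had 11 of 15 higher over all genes and 15 over the list alone (median log2 2.37, 2.24 with the block, 2.42 in spike-in arrays, adjusted p = 1.6e-10, adjusted p = 0.276 with an estimated correlation). Heat shock and protein folding genes had 12 of 20 higher over all genes and 15 over the list alone (median log2 1.30, 1.22 with the block, 1.46 in spike-in arrays, adjusted p = 7.6e-11, adjusted p = 0.276 with an estimated correlation). Carbon-limitation transport and catabolism genes were lower, with 24 of 55 lower over all genes and 33 over the list alone (median log2 −1.47, −1.38 with the block, −1.09 in spike-in arrays, adjusted p = 6.6e-14, adjusted p = 0.278 with an estimated correlation). Of these, lamB (b4036) was lower at log2 −4.10 ± 0.69. Fatty acid degradation genes had 7 of 9 lower over all genes and 9 over the list alone (median log2 −2.58, −2.49 with the block, −1.96 in spike-in arrays, adjusted p = 1.5e-07, adjusted p = 0.298 with an estimated correlation). Of these, fadB (b3846) changed by log2 −5.07 ± 0.91.

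By limma, 465 probe sets were higher and 275 lower in knock-out biofilm than in stationary phase, 669 of them by at least 2-fold, in 310 and 194 genes. The groups did not overlap in 33.2% of probe sets. The count was 691 with the block, and within the spike-in arrays 312 were higher and 110 lower. It was 473, 464 and 459 without knock-out biofilm replicates 1, 2 and 3, and 1141, 455 and 493 without knock-out stationary replicates 1, 2 and 3. Of 17 called lists, 16 kept the call with the block and 14 within the spike-in arrays.

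Between stationary and exponential phase of the knock-out, rpoS stayed near background, and limma called 0 probe sets, with 532 at an unadjusted p under 0.05. In 3.9% of probe sets the groups did not overlap, against 10% by chance. With the block and within the spike-in arrays the count stayed at 0, but both groups held 2 spike-in arrays, so the block can alter only the residual spread here. Within the arrays without spike-in RNA each group held 1 array, so no count is read there. The count was 36 without knock-out exponential replicate 1 and 362 without knock-out stationary replicate 1. Flagellar and chemotaxis genes had 0 of 54 lower over all genes and 14 over the list alone (median log2 −0.67, −0.59 in spike-in arrays, −1.29 in arrays without spike-in, −1.26 without the replicate 1 arrays of both groups, adjusted p = 1.3e-12, adjusted p = 0.547 with an estimated correlation). Histidine biosynthesis genes had 0 of 8 lower over all genes and 7 over the list alone (median log2 −1.64, −0.65 in spike-in arrays, −3.67 in arrays without spike-in, −2.79 without the replicate 1 arrays of both groups, adjusted p = 1.5e-06, adjusted p = 0.547 with an estimated correlation). In all 12 lists were called by the preset correlation.

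The knock-out effect on rpoS had a difference of log2 0.38 ± 0.83 between biofilm and stationary phase and was not called (adjusted p = 0.758). It differed at grxA (difference of log2 6.48 ± 0.68, adjusted p = 4.3e-05, n = 3 per group), gadA (log2 5.51 ± 1.28, adjusted p = 9.6e-03) and sdhB (log2 −5.24 ± 0.93, adjusted p = 1.9e-03). The oxidoreductase gene dkgA (b3012) differed by 4.82 ± 0.42 and the quinone reductase gene wrbA (b1004) by 4.8 ± 0.91. General stress genes that depend on RpoS were less lowered in biofilm, with 35 of 71 positive over all genes and 38 over the list alone (median log2 1.88, 2.01 with the block, adjusted p = 2.2e-18, adjusted p = 0.427 with an estimated correlation). Acid resistance genes of the Gad list differed in the direction of biofilm, with 9 of 15 positive over all genes and 14 over the list alone (median log2 3.10, 2.95 with the block, adjusted p = 9.6e-09, adjusted p = 0.529 with an estimated correlation). Genes of heat shock and protein folding had 13 of 20 positive over all genes and 14 over the list alone (median log2 2.22, 2.17 with the block, adjusted p = 1.5e-11, adjusted p = 0.427 with an estimated correlation). TCA cycle and glyoxylate shunt genes went the other way, with 10 of 18 negative over all genes and 16 over the list alone (median log2 −2.15, −2.0 with the block, adjusted p = 8.9e-06, adjusted p = 0.701 with an estimated correlation). In total 566 probe sets had a positive and 751 a negative difference, 1424 in all with the block. The count was 847, 823 and 800 without knock-out biofilm replicates 1, 2 and 3, 2164 without wild-type biofilm replicate 1 and 766 without wild-type stationary replicate 1. The positive share was 43.0%, and 59.0% with quantile normalization.

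Between biofilm and exponential phase the difference for rpoS was log2 1.87 ± 0.83 (adjusted p = 0.103). The knock-out effect differed at gadA (log2 6.21 ± 1.28, adjusted p = 5.6e-03), gadW (log2 5.22 ± 0.76, adjusted p = 1.1e-03), pyrL (log2 5.5 ± 0.83, adjusted p = 1.1e-03) and, in the other direction, yjfN (log2 −4.66 ± 1.08, adjusted p = 9.8e-03). Gad acid resistance genes had 12 of 15 positive over all genes and 13 over the list alone (median log2 3.43, 3.32 with the block, adjusted p = 2.8e-08, adjusted p = 0.468 with an estimated correlation). Pyrimidine biosynthesis genes had 9 positive and 1 negative of 12 over all genes, 11 and 1 over the list alone (median log2 3.45, 3.79 with the block, adjusted p = 7.1e-06, adjusted p = 0.468 with an estimated correlation). Purine biosynthesis genes had 8 of 16 positive over all genes and 14 over the list alone (median log2 2.75, 3.13 with the block, adjusted p = 8.1e-07, adjusted p = 0.468 with an estimated correlation). Ribosomal protein genes had 9 of 54 positive over all genes and 8 over the list alone (median log2 1.54, 1.90 with the block, 0.69 after quantile normalization, adjusted p = 1.4e-10, adjusted p = 0.597 with an estimated correlation). In total 837 probe sets had a positive and 915 a negative difference, 2091 in all with the block. The count was 1086, 1073 and 1011 without knock-out biofilm replicates 1, 2 and 3, and 1026 and 945 without wild-type exponential replicates 1 and 3. The positive share was 47.8%, 53.3% with quantile normalization and 26.2% with 75th percentile centring. Positive differences were the more numerous with the block (1083 and 1008), at 2-fold (822 and 729) and without the dimmest 25% (812 and 595).

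Between stationary and exponential phase the difference for rpoS was log2 1.49 ± 0.83 (adjusted p = 0.279). The knock-out effect was called different at cyoA (log2 6.09 ± 0.82, adjusted p = 2.1e-04), atpB (log2 5.76 ± 0.78, adjusted p = 2.3e-04), livJ (log2 5.53 ± 0.51, adjusted p = 2.8e-05) and, in the other direction, yjbJ (log2 −4.60 ± 0.55, adjusted p = 1.0e-04). RpoS-dependent general stress genes were lowered further in stationary phase, with 1 positive and 22 negative of 71 over all genes, 1 and 24 over the list alone (median log2 −1.03, −1.08 in arrays without spike-in, −1.70 after quantile normalization, adjusted p = 3.1e-10, adjusted p = 0.475 with an estimated correlation). The block cancels from these medians by construction. ATP synthase genes all differed, with 9 of 9 positive over all genes and 9 over the list alone (median log2 4.20, 4.28 in arrays without spike-in, adjusted p = 2.8e-10, adjusted p = 0.333 with an estimated correlation). NADH dehydrogenase I genes had 13 of 13 positive over all genes and 13 over the list alone (median log2 3.19, 3.61 in arrays without spike-in, adjusted p = 6.8e-13, adjusted p = 0.333 with an estimated correlation). Genes of the TCA cycle and glyoxylate shunt had 15 of 18 positive over all genes and 15 over the list alone (median log2 3.13, 4.41 in arrays without spike-in, adjusted p = 2.4e-10, adjusted p = 0.413 with an estimated correlation). Ribosomal protein genes had 38 of 54 positive over all genes and 46 over the list alone (median log2 2.75, 3.09 in arrays without spike-in, adjusted p = 1.6e-17, adjusted p = 0.475 with an estimated correlation). Purine biosynthesis genes had 15 of 16 positive over all genes and 16 over the list alone (median log2 3.41, 3.38 in arrays without spike-in, adjusted p = 9.9e-10, adjusted p = 0.413 with an estimated correlation). In total 811 probe sets had a positive and 333 a negative difference, 1289 in all with the block. The positive share was 70.9%, with quantile normalization 54.4% and with 75th percentile centring 47.7%.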

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

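The tests of exchanged arrays, of the spike-in block and of scaling for the first pattern, of wild-type biofilm replicate 1 and scaling for the Gad genes, and of the spike-in block and scaling for the ribosomal, ATP synthase, NADH dehydrogenase and TCA genes were chosen only after the results were seen.

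The difference in knock-out effect between growth conditions was itself tested at each probe set, and it drew attention at 1317 probe sets for biofilm minus stationary phase, 1752 for biofilm minus exponential phase and 1144 for stationary minus exponential phase. As many were called in 4, 3 and 2 of 100 drawn splits of the arrays into strains, the real split included. Most splits also break up the strain effect, so these shares, though under the 0.05 set beforehand, cannot exclude chance. The highest other splits gave 3336, 1889 and 1383. Those of 3336 and 1383 exchanged whole groups. Splits that broke up groups gave up to 1507, 1889 and 994, the first 2 above the real counts. For lists called in these differences (12, 19 and 17), chance cannot be excluded, since 68, 20 and 21 of 100 splits gave as many, with 24, 22 and 20 as the highest others.

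Between stationary and exponential phase of the knock-out, 0 probe sets were called. The block alters only the residual spread here, so 0 calls with it decide nothing about the spike-in batch. Scaling is argued against, since the most called under 2 scalings was 0. Exchanging replicate 1 of the 2 groups gave 1024 called probe sets, against 153 in the next highest of the 10 splits, so an exchange of these arrays stays open. A similar growth state stays open as well: over 1499 genes on a line from wild-type exponential (0) to wild-type stationary phase (1), the knock-out means were 0.132 ± 0.071 and 0.272 ± 0.187, only 0.139 apart. With the arrays exchanged the means would still be only 0.233 apart, so this line cannot tell these last 2 apart. If the arrays were exchanged, 1024 probe sets would differ, and a similar growth state would not be the reason for 0 calls. The line leaves out the RpoS list but may hold other genes that fell in the knock-out, so a position need not reflect growth alone.

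Gad acid resistance genes stood out because the knock-out effect differed by a median of log2 3.10 between biofilm and stationary phase and 3.43 between biofilm and exponential phase. Their rise in the knock-out biofilm rests in part on wild-type biofilm replicate 1, where the median Gad intensity was 227 against 1787 and 1932, since without it the median change was 0.64. As the cause of the 3.10, that array alone (2.38 without it) and scaling (3.04 after quantile normalization) are argued against. The block partly cancels here, so 2.95 with it cannot decide on the spike-in batch. In the knock-out, the median Gad intensity was 2394 to 2516 in biofilm and 51.7 to 190 in the planktonic phases. A biofilm-specific path to Gad expression without RpoS remains a hypothesis, found on these arrays and not tested.

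The 94 measured members of the ribosomal protein, ATP synthase, NADH dehydrogenase I and TCA cycle lists had a median of log2 2.64 in the stationary knock-out over the wild type. Within the arrays without spike-in RNA it was 2.47, but there the knock-out had 1 array, which decides nothing about the batch. The spike-in batch is argued against by 1.92 with the block, exponential RNA on knock-out stationary replicate 1 by 2.27 without that array, and scaling by 2.15 after quantile normalization. In the 3 settings with the block, without that array and after quantile normalization, 90 of the 94 genes were higher. A knock-out culture that had not entered the wild-type stationary state at 12 h is a hypothesis that may account for this, found on the same arrays and with growth not measured in the files used here.

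Heat shock and protein folding genes drew attention by a tested difference of 2.22 between the knock-out effects in biofilm and stationary phase. Ribosomal protein genes did so by 1.54 (biofilm minus exponential phase) and 2.75 (stationary minus exponential phase). Purine biosynthesis genes did so by 2.75 and 3.41 in the same comparisons, and pyrimidine biosynthesis genes by 3.45 for biofilm minus exponential phase. Dap spike-in RNA, a signal outside the main measurement, was present on 9 of the 18 arrays, in part of 3 groups, all of 1 and none of 2.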

How the results depend on the processing

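The spike-in block, the fits within arrays with or without spike-in RNA and the fit without knock-out exponential and stationary replicate 1 were tests chosen only after the results were seen.

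No named gene with a call reversed direction and no list was called the other way, and the fall of rpoS in the knock-out kept its call in every fit. The balance of higher and lower probe sets did turn with scaling: from 31.0% higher to 67.6% for wild-type stationary over exponential phase and from 61.3% to 45.0% for the strains in stationary phase (75th percentile centring), and from 69.3% to 45.5% for wild-type biofilm over stationary phase (quantile normalization). It also turned at 2-fold and without wild-type biofilm replicate 3, for the strains in biofilm (1106 higher and 1057 lower, 1495 and 1460) and for wild-type biofilm over exponential phase (1158 and 1379, 1511 and 1798), and for biofilm minus stationary or exponential phase without any 1 of the knock-out biofilm arrays or some others. Of the 191 list calls, 0 were kept with the estimated correlation, 190 with the replicate block, 178 with the spike-in block, 168 with quantile normalization and 186 with 75th percentile centring. A list median changed sign in 1 case each with the spike-in block, within the spike-in arrays and with quantile normalization. Named genes (716 values) lost their calls in 22 cases with an added constant of 1, 34 with 64, 50 with quantile normalization, 7 with 75th percentile centring, 39 with the replicate block, 42 with the spike-in block, 97 with only the groups compared and 146 with any 1 array left out. Within the spike-in arrays 63 lost the call and 140 kept it, and without the 2 doubted arrays 29 and 358.

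With only 1-symbol probe sets, fewer were tested and fewer called: 1842, 123 and 1268 for the strains in biofilm, exponential and stationary phase, 2038, 1230 and 1544 for wild-type biofilm over exponential, biofilm over stationary and stationary over exponential phase, and 254 for knock-out biofilm over exponential phase. It left 847, 925 and 738 for the differences (biofilm minus stationary, biofilm minus exponential, stationary minus exponential), and 426 higher and 172 lower in wild-type biofilm than in both phases. A fold of at least 2, stricter by construction, left 1363 for wild-type biofilm over stationary phase, 345 higher than in both phases and 155 lower in the knock-out in both biofilm and stationary phase.

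For the other moves the cause was not tested. With only the groups compared, which also changes the residual variance, the counts were 140 (strains, exponential phase), 994 (wild-type biofilm over stationary phase) and 4109 (wild-type stationary over exponential phase). With 75th percentile centring 3961 were called for wild-type stationary over exponential phase, 3132 for biofilm minus exponential phase, and 714 were lower in the knock-out in both biofilm and stationary phase. Higher than in both phases were 478 with quantile normalization and 456 without the dimmest 25%. The spike-in block gave 460 (strains, exponential phase), 1356 (wild-type biofilm over stationary phase), 458 (higher than in both), 74 lower in all 3 conditions and 96 lower in biofilm and exponential phase. Within the arrays without spike-in RNA, fewer by construction, the counts were 2609, 3238, 4109, 2422 and 2598 (strains in exponential and stationary phase, stationary over exponential phase in the wild type and the knock-out, stationary minus exponential phase), 1042 lower than in both and 398 lower in the knock-out in both planktonic phases. Within the spike-in arrays knock-out biofilm over stationary phase gave 422. Without the 2 doubted arrays the knock-out gave 1297 for biofilm over stationary phase and 878 for stationary over exponential phase.

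With the replicate number as a block the counts were 3030, 201 and 1849 for the strains in biofilm, exponential and stationary phase, and no count moved by over 1.5 times. Of 45 pairs of arrays with the same number, 8 correlated over 0.1 and 27 under 0 (−0.418 to 0.253), so the numbers do not pair the arrays.

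With 1 array left out in turn, counts ranged from 105 to 268 (strains, exponential phase), 1048 to 2832 (wild-type biofilm over stationary phase), 238 to 490 and 455 to 1141 (knock-out biofilm over exponential and over stationary phase), and 0 to 362 (knock-out stationary over exponential phase). They ranged from 766 to 2164 and 945 to 2336 for the differences biofilm minus stationary and biofilm minus exponential phase, and from 358 to 1311 for higher in wild-type biofilm than in both. Fewer arrays lower the precision by construction, and the cause of the rises was not tested.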

Other observations

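The tests described in this part were planned, and only the spike-in block and fits within 1 kind of array were tests chosen after the results were seen.

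Between wild-type stationary and exponential phase, tryptophan biosynthesis genes had 5 of 7 lower over all genes and 6 over the list alone (median log2 −2.85, adjusted p = 9.1e-03, adjusted p = 0.479 with an estimated correlation). Of these, trpA (b1260) changed by log2 −3.55 ± 0.48 and trpD (b1263) by −3.30 ± 0.67. Methionine biosynthesis genes had 10 of 14 lower over all genes and 10 over the list alone (median log2 −2.73, adjusted p = 6.3e-03, adjusted p = 0.560 with an estimated correlation). Of these, the methionine uptake gene metQ (b0197) changed by log2 −4.70 ± 0.79 and metK (b2942) by −4.12 ± 0.87. Histidine biosynthesis genes had 7 of 8 lower over all genes and 7 over the list alone (median log2 −3.07, adjusted p = 7.9e-03, adjusted p = 0.560 with an estimated correlation). Of these, hisC (b2021) changed by log2 −3.58 ± 0.72. Cysteine and sulphate assimilation genes had 0 higher and 11 lower of 20 over all genes, 1 and 11 over the list alone (median log2 −2.19, adjusted p = 0.0267, adjusted p = 0.604 with an estimated correlation). Of these, cysN (b2751) changed by log2 −3.81 ± 0.82. The toxin gene mqsR (b3022) and its antitoxin gene mqsA (b3021) rose by log2 2.59 ± 0.45 and 2.19 ± 0.45.

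In the knock-out, phage shock genes were higher in biofilm than in exponential phase, with 2 of 7 higher over all genes and 4 over the list alone (median log2 1.46, 1.31 with the block, 1.64 in spike-in arrays, adjusted p = 1.9e-03, adjusted p = 0.533 with an estimated correlation). Of these, pspG (b4050) rose by log2 2.57 ± 0.41. Cysteine and sulphate assimilation genes were higher in knock-out biofilm than in stationary phase, with 8 of 20 higher over all genes and 12 over the list alone (median log2 1.79, 1.34 with the block, 1.5 in spike-in arrays, adjusted p = 1.8e-06, adjusted p = 0.414 with an estimated correlation). Of these, cysW (b2423) rose by 3.09 ± 0.48. The cell division inhibitor gene sulA (b0958) of the SOS response had a difference of knock-out effects of 4.04 ± 0.37 between biofilm and stationary phase. Curli fibre, cold shock and multidrug efflux genes were called in no comparison.

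Other splits of the same arrays were counted for the remaining comparisons. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The counts of probe sets, with the highest other split, were 3233 and 0 (strains, biofilm), 230 and 0 (exponential phase), 1947 and 0 (stationary phase), 3604 and 0 (wild-type biofilm over exponential phase), 2123 and 7 (over stationary phase), 2462 and 1 (stationary over exponential phase), 402 and 1 (knock-out biofilm over exponential phase) and 740 and 1 (over stationary phase), where only 1 of the 10 splits, the real split, gave as many. For knock-out stationary over exponential phase all 10 did (0 and 1024). The counts of lists in the same order were 22 and 20, 13 and 16, 16 and 22, 14 and 17, 12 and 15, 21 and 22, 16 and 16, 17 and 17, and 12 and 14, with 1, 6, 6, 6, 4, 5, 2, 2 and 5 of 10 splits giving as many. Of 100 drawn splits, 1 gave as many probe sets lower in the knock-out in all 3 conditions (45, highest other 0), but a 0 was bound to follow, since the other splits of each strain comparison called 0. For wild-type biofilm against both phases, 3 of 100 gave as many higher (868, highest other 1137) and 3 as many lower (303 and 372). Both shares are under 0.05 but cannot exclude chance, as the splits also mix the planktonic phases. The highest others exchanged whole groups, but broken groups gave up to 1082 higher and 319 lower, above the real counts.

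The closest array to knock-out stationary replicate 1 was knock-out exponential replicate 3 (r = 0.979), and knock-out exponential replicate 1 and knock-out stationary replicate 3 were closest to each other (r = 0.944).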
